A study of Arabidopsis thaliana with 15 samples.

How the data were processed

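RNA-seq was carried out on the aboveground parts of Arabidopsis thaliana plants of the accession Col-0 in 15 libraries, 3 for each of 5 groups, 96 h after spraying with a bacterial suspension or with phosphate-buffered saline. Each library was a pool of 2 plants taken from different growth boxes, so the replicates were separate sets of plants. Per the labels' protocols, poly-A RNA was made into libraries with the NEBNext Ultra RNA kit and sequenced as paired ends on an Illumina NovaSeq instrument.

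The values used here were raw counts of reads per gene, deposited by the authors in 1 table for all libraries. Per the submitters' processing notes, cutadapt 1.9.1, featureCounts 1.22.2 and the genome build TAIR10 were used. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and of a partner that overlaps it on the opposite strand were therefore treated as not separable. All columns of the table matched the title of 1 library each, with 0 columns left unmapped, and 0 entries of the table named no gene. The table held 32833 gene identifiers, of which 32548 matched a RefSeq gene table for the assembly TAIR10.1. That table was used for symbols and for the share of each gene's exon bases that no other gene covers, and none of its coordinates are given. Named genes with under 95% of exon bases of their own, and members of near-identical families, are given as uncertain.

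Library totals ran from 17811560 to 21870246 counts. The 10 most abundant genes took 7.03% to 9.51% of the counts, and the scaling factors of the trimmed mean of M values (TMM) ran from 0.958 to 1.03. No library was counted once for another: the closest pair within a group, W8 replicates 1 and 3, differed by a chi-square of 3.96 per degree of freedom, where sampling noise alone gives about 1.

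Groups, comparisons, gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group factor (minimum count 10, minimum total 15), which left 19404 genes and removed 13429, and 7521 of those removed were at 0 in all libraries. After TMM scaling, dispersions were estimated with estimateDisp and genes were tested with glmQLFit (robust=TRUE) and glmQLFTest in a model with 1 mean per group over all 15 libraries. P values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. The comparisons were each density against mock, each density against the next lower one, the highest against the lowest, and a test with 4 degrees of freedom for any difference among the 5 groups. A slope on log10 density was fitted to the 12 inoculated libraries, in which 19285 genes passed the filter. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. Expression levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over the 3 libraries of a group.

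A total of 22 gene lists were fixed from textbook roles: pattern-triggered immunity, salicylic acid, systemic acquired resistance and N-hydroxypipecolic acid, camalexin and indole phytoalexins, indole glucosinolates, aliphatic glucosinolates, jasmonic acid, ethylene, cysteine-rich and wall-associated receptor kinases, endoplasmic reticulum protein folding, heat shock, abscisic acid and cold or drought, light harvesting and carbon fixation, iron deficiency, phosphate starvation, flavonoids and anthocyanins, auxin response, cell cycle, senescence, circadian clock, root markers and flower markers. For each list the members called by the gene test were counted, adjusted over all genes and adjusted over the list alone. Lists were also tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and with an estimated one, and p values were adjusted by Benjamini-Hochberg over the 22 lists of a comparison. Against mock, camera also called at least as many lists in some regrouped libraries as in the real groups, so statements about groups of genes rest on the counts of members called by the gene test.

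The genes named were, for each density against mock, up to 10 rising and 10 falling genes with the largest absolute log2 fold change among those called, with an average log2 CPM of at least 1 and with all 3 inoculated libraries on the same side of all 3 mock libraries. For each step between densities up to 3 per direction were taken by the same criteria, and for the slope up to 5 per direction among those called with an average log2 CPM of at least 1. From each list up to 4 members with the smallest p in W8 against mock were taken, whether called or not, and PR1, PR2, PR5, FRK1, PAD3, CYP71A13, FMO1, ICS1, WRKY33, PDF1.2, VSP2 and LHCB1.1 were always included. Genes named outside this rule are said to be chosen after their values were seen.

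The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors within edgeR, upper-quartile scaling, no filter except on genes at 0, a stricter filter (at least 10 counts in at least 3 libraries and a total of 100), robust=FALSE, limma voom, the replicate number as a block, a fit of only the 2 groups compared, an added requirement of an absolute log2 fold change of at least 1, mock to W8 scored 0 to 4 in place of the slope, and leaving out each replicate in turn. A fit without mock replicate 3 and W8 replicate 2 was added after seeing that both stood apart from their groups. The 4 comparisons against mock share its libraries, so their fold changes were set beside 100 simulations of unchanged groups against a shared mock group.

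Each step was tested on simulated data drawn from the means and sizes of these libraries. For W8 against mock, over 19225 genes, edgeR called 74% of genes raised by a log2 fold change of 1, 78% of those lowered by 1, 100% of those raised by 2 and 94% of those lowered by 2, with 9 unchanged genes called. DESeq2 called 80%, 80%, 100% and 96% of the same classes over 19404 genes with 20 unchanged genes called, and limma voom 80%, 80%, 98% and 94% with 9. For the slope, over 19185 genes, edgeR called 90% of slopes of 0.5, 92% of slopes of -0.5 and 100% of slopes of 1 and of -1, with 17 unchanged genes called. For any difference among the 5 groups, over 19244 genes, it called 78%, 84%, 100% and 94% of genes raised or lowered by 1 and raised or lowered by 2, in that order, with 15 unchanged genes called. Camera called 2 of 2 lists raised by a log2 value of 0.5 in W8 against mock over 19404 genes, and 0 unchanged lists, with either correlation. These simulated genes varied independently of each other.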

Results

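Williamsia sp. Leaf354 is a bacterium from leaves that causes no disease. Arabidopsis thaliana Col-0 plants aged 6 weeks, grown in boxes on ground zeolite, were sprayed with it at 100000, 1000000, 10000000 or 100000000 CFU/ml, called W5, W6, W7 and W8 after the log10 density, or with buffer as mock. The aboveground parts were taken 96 h later. The title of the series poses the question of whether plant immunity answers such bacteria according to how many are applied. Each group had 3 libraries, and the totals per library ran from 18690766 to 21648036 counts in mock, 19107869 to 21333041 in W5, 18200020 to 20980193 in W6, 18438508 to 21669178 in W7 and 17811560 to 21870246 in W8.

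Over the 19404 genes tested, 6380 differed among the 5 groups. The first principal component of log2 CPM held 49.7% of the variance and rose from W5 (-34.2 to -29.3) through W6 (-19.8 to -12.3) and W7 (-3.94 to 25) to W8 (49.1 to 75.5). Mock replicates 1 and 2 lay at -42.4 and -39.8. Mock replicate 3 stood apart from them at 19.4, within the range of W7, and at 50 on the second component, which held 9.17%.

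**Figure D1:**
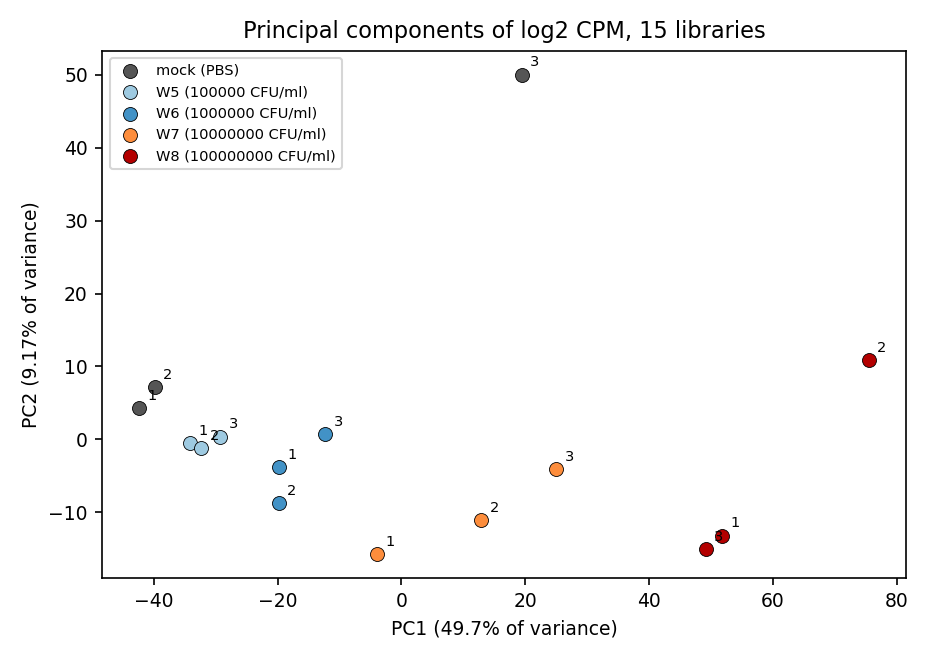
Each point is 1 library, placed by its first (49.7% of the variance) and second (9.17%) principal component of log2 CPM over the 19404 genes tested. The inoculated groups follow their density along the first component, and mock replicate 3 lies apart from the other mock libraries.

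At W5, the lowest density, a small set of genes differed from mock, led by genes of little known function. AT2G20670, a gene of the DUF506 family, rose by a log2 fold change of 1.57 ± 0.088 (SE, n = 3 per group; adjusted p = 6.36e-09), from 38.1 ± 1.68 to 113 ± 11.1 CPM. AT1G80440, which encodes the kelch-repeat F-box protein KMD1 that turns over activators of the cytokinin response, rose by 1.19 ± 0.085 (adjusted p = 2.34e-07). AT3G18773, which encodes a RING finger protein and shares exon bases with another gene, rose by 1.28 ± 0.13 (adjusted p = 3.05e-05, uncertain for that reason), and AT3G07350, also of the DUF506 family, by 1.25 ± 0.17 (adjusted p = 0.00161). Smaller rises were found for AT2G25200 of the DUF868 family (0.76 ± 0.082, adjusted p = 5.4e-05) and for RMA1 (AT4G03510), a membrane-anchored ubiquitin ligase (0.71 ± 0.075, adjusted p = 5.4e-05; uncertain, since it shares exon bases). AT5G19120, which encodes an aspartyl protease, rose by 1.27 ± 0.12 (adjusted p = 5.4e-05), and AT5G50450, which encodes a MYND zinc finger protein, by 0.82 ± 0.12 (adjusted p = 0.0034), though neither passed in a fit of only these 2 groups (adjusted p = 0.0681 and 0.0765).

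The 3 genes lower at W5 were AT2G44940, ARR6 and AT2G41410. AT2G44940, a transcription factor gene of the AP2/ERF family, fell by 0.63 on the log2 scale (SE 0.12, adjusted p = 0.0324). ARR6 (AT5G62920), a cytokinin-induced response regulator that shares exon bases with another gene, fell by 0.60 (SE 0.12, adjusted p = 0.0382), and AT2G41410, which encodes an EF-hand protein, by 0.47 (SE 0.081, adjusted p = 0.0134). AT2G44940 had adjusted p values of 0.214, 0.23, 0.0862, 0.223 and 0.218 without mock replicates 1 and 2 and W5 replicates 1, 2 and 3, in that order, and ARR6 had 0.19, 0.247, 0.262, 0.224 and 0.129 without the same libraries. AT2G41410 had 0.127, 0.0804 and 0.129 without mock replicate 2 and W5 replicates 1 and 3. In a fit of only these 2 groups AT2G44940 (0.144) and AT2G41410 (0.0765) did not pass, and with robust=FALSE AT2G44940 (0.0698) and ARR6 (0.0833) did not.

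In all, 35 genes passed at W5, 32 higher and 3 lower, of which 7 changed at least 2-fold, and 1186 had an unadjusted p under 0.05. The count was 18, 18 and 60 without mock replicates 1, 2 and 3, and 15 and 17 without W5 replicates 1 and 3. It was 58 with DESeq2 (43 higher, 15 lower), 14 in a fit of only these 2 groups and 78 without mock replicate 3 and W8 replicate 2, a fit added after seeing the data. Of the 275 list members tested, edgeR called 0 at W5, with 19 at an unadjusted p under 0.05 (4 higher, 15 lower), while DESeq2 called 1 and limma voom 0. Adjusted over the list alone, 1 member of 1 list passed, the senescence regulator NAP (AT1G69490) at a log2 fold change of 0.53 (adjusted p = 0.00312). It was also the member called by DESeq2 (adjusted p = 0.00379) and by edgeR without mock replicate 3 (log2 fold change 0.74, adjusted p = 5.19e-05). Camera called 6 lists with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.988 with an estimated correlation).

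The rises at W6 included BT2 and SEN1. BT2 (AT3G48360), a BTB and TAZ domain protein that answers sugar and nitrogen supply, stood at 4.32 ± 1.53 CPM in mock and 4.13 ± 0.686 at W5, and reached 21.6 ± 0.643 at W6 (log2 fold change against mock 2.30 ± 0.22, adjusted p = 7.18e-05). AT2G20670 rose by 2.73 ± 0.09 (adjusted p = 4.26e-13), AT5G19120 by 2.14 ± 0.12 (adjusted p = 3.18e-08), AT1G80440 by 2.07 ± 0.086 (adjusted p = 1.51e-11) and AT3G07350 by 2.02 ± 0.16 (adjusted p = 1.07e-06). SEN1 (AT4G35770), a gene induced by darkness and sugar loss, rose by 1.92 ± 0.25 (adjusted p = 0.00201), OXS3 (AT5G56550), named for oxidative stress tolerance, by 2.34 ± 0.24 (adjusted p = 8.96e-05) and AT5G21940 by 2.77 ± 0.30 (adjusted p = 0.000516; uncertain, since it shares exon bases). In a fit of only these 2 groups SEN1, OXS3 and AT5G21940 had adjusted p values of 0.0634, 0.0654 and 0.17.

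Genes tied to cytokinin were among those that fell at W6. ARR6 fell by 1.27 on the log2 scale (SE 0.12, adjusted p = 2.27e-06), from 28.6 ± 1.65 to 11.8 ± 2.36 CPM, and ARR7 (AT1G19050), another response regulator of the same class, by 0.81 (SE 0.13, adjusted p = 0.00251). AT2G44940 fell by 1.14 (SE 0.12, adjusted p = 1.31e-05), KUF1 (AT1G31350), an F-box gene induced by karrikins, by 0.89 (SE 0.16, adjusted p = 0.00457), and CP1 (AT5G49480), a calcium-binding protein gene, by 0.78 (SE 0.13, adjusted p = 0.00327). CRF5 (AT2G46310), a cytokinin response factor, fell by 1.06 (SE 0.24, adjusted p = 0.0284), and CYP78A6 (AT2G46660), a cytochrome P450 gene, by 0.80 (SE 0.18, adjusted p = 0.0248). CRF5 did not pass without mock replicate 2 (0.0565), mock replicate 3 (0.0869), W6 replicate 2 (0.185) or W6 replicate 3 (0.189), nor in a fit of only these 2 groups (0.194) or without mock replicate 3 and W8 replicate 2 (0.0756). CYP78A6 had 0.078, 0.16, 0.167 and 0.146 without mock replicates 1 and 2 and W6 replicates 2 and 3, and 0.0739 in that fit.

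In all, 249 genes passed at W6, 183 higher and 66 lower, 57 of them at least 2-fold, and 2121 had an unadjusted p under 0.05. The count was 156 and 469 without mock replicates 2 and 3, and 161 and 147 without W6 replicates 2 and 3. It was 145 in a fit of only these 2 groups and 577 without mock replicate 3 and W8 replicate 2.

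Among the lists at W6, edgeR called members of the senescence list, 2 higher of 7, with 4 adjusted over the list alone. The 2 genes were NAP (1.01 ± 0.12, adjusted p = 0.000129) and ORE1 (AT5G39610; 1.00 ± 0.16, adjusted p = 0.00471), a pair of NAC transcription factors that promote leaf senescence, and ORE1 had an adjusted p of 0.0527 in a fit of only these 2 groups. PPH (AT5G13800) and PAO (AT3G44880), enzymes of chlorophyll breakdown, passed over the list alone (0.21 and 0.15). The other 21 lists had 0 members called by edgeR, and the 22 lists had 49 members at an unadjusted p under 0.05 (20 higher, 29 lower), while DESeq2 called 8 members and limma voom 2. DESeq2 added LHY (AT1G01060), PRR9 (AT2G46790), CCA1 (AT2G46830), PPSPASE1 (AT1G73010), FRK1 (AT2G19190) and AZI1 (AT4G12470), of which FRK1 (1.54, adjusted p = 0.00195) and AZI1 (0.46, adjusted p = 0.00369) were higher and the others lower. Adjusted over the list alone, 1 systemic acquired resistance gene was higher (AZI1), 3 aliphatic glucosinolate genes lower (CYP79F2, AT1G16400; SOT17, AT1G18590; MAM3, AT5G23020), 2 cell cycle genes higher (PCNA1, AT1G07370; CYCD3;1, AT4G34160) and 3 clock genes lower (LHY, PRR9 and CCA1). Without mock replicate 3 edgeR called FRK1, MLO12 (AT2G39200), ERF6 (AT4G17490) and PPH higher, and SQD2 (AT5G01220), SPX3 (AT2G45130), RBCS3B (AT5G38410), PRR9 and CCA1 lower. LHY and MAM3 were called lower without mock replicate 2. Without W6 replicate 1, SOT17 and UGT74B1 (AT1G24100) were called lower and AZI1 and GH3.5 (AT4G27260) higher. With upper-quartile scaling, and in a fit of only these 2 groups, 1 systemic acquired resistance gene was called, and with robust=FALSE 1 gene of pattern-triggered immunity. W6 replicate 1 had 32 genes over 2-fold above every other library. These list members outside the rule for named genes were chosen after their values were seen. Camera called 6 lists with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.181 with an estimated correlation, for the senescence list).

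At W7, BT2 reached 64.4 ± 4.76 CPM (log2 fold change against mock 3.88 ± 0.21, adjusted p = 1.66e-07) and AT2G20670 346 ± 10 CPM (3.18 ± 0.091, adjusted p = 3.32e-14). AT5G64190 rose by 3.25 ± 0.27 (adjusted p = 1.49e-07), SEN1 by 2.75 ± 0.25 (adjusted p = 4.26e-05) and AT5G21940 by 2.77 ± 0.30 (adjusted p = 0.00019). A pair of genes for proteins with cysteine- and histidine-rich C1 domains, AT2G17740 and AT2G44370, rose by 2.91 ± 0.44 and 2.67 ± 0.40 (adjusted p = 0.00128 and 0.00036), and AT2G43620, which encodes a chitinase, by 2.72 ± 0.43 (adjusted p = 0.00256). AT3G15450 rose by 2.62 ± 0.43 (adjusted p = 0.00322), though not in a fit of only these 2 groups (0.0897).

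Genes that fell at W7 included AT2G44940 (log2 fold change -1.94 ± 0.13, adjusted p = 9.16e-09) and TINY2 (AT5G11590; -1.66 ± 0.25, adjusted p = 0.000209), both of the AP2/ERF family. The auxin-responsive SAUR-like gene AT1G75580 fell by 1.65 (SE 0.22, adjusted p = 5.17e-05), CP1 by 1.40 (SE 0.14, adjusted p = 3.1e-06), BBX29 (AT5G54470), a B-box zinc finger gene, by 1.40 (SE 0.16, adjusted p = 9.75e-06) and AT1G76240 by 1.34 (SE 0.12, adjusted p = 2.06e-07). CRF5 fell by 1.24 (SE 0.24, adjusted p = 0.00215) and ARR6 by 0.80 (SE 0.12, adjusted p = 0.000174). AT2G15020 fell by 1.85 (SE 0.27, adjusted p = 0.00141), but had an adjusted p of 0.0647 in a fit of only these 2 groups.

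In all, 2534 genes passed at W7, 1221 higher and 1313 lower, 250 of them at least 2-fold, and 5394 had an unadjusted p under 0.05. The count was 1253, 1120 and 3866 without mock replicates 1, 2 and 3, and 1164 and 1662 without W7 replicates 2 and 3. It was 4158 without mock replicate 3 and W8 replicate 2. Which direction held more genes depended on the setting. Higher genes outnumbered lower ones without the filter (1180 and 1101), in a fit of only these 2 groups (952 and 804), without mock replicates 1 (716 and 537), 2 (679 and 441) and 3 (1952 and 1914) and without W7 replicates 1 (1138 and 1053), 2 (707 and 457) and 3 (928 and 734). Of the genes changed at least 2-fold, 201 were higher and 49 lower.

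Immune genes were called at W7. FRK1, a receptor kinase gene used as a marker of pattern-triggered immunity, rose by 2.42 ± 0.36 (adjusted p = 0.00173), from 4.81 ± 2.6 to 26.2 ± 7.86 CPM. The salicylic acid receptor genes NPR3 (AT5G45110) and NPR4 (AT4G19660) rose by 0.75 ± 0.16 and 0.57 ± 0.10 (adjusted p = 0.00799 and 0.000814), with 0.0789 for NPR3 in a fit of only these 2 groups. AZI1 and EARLI1 (AT4G12480), tandem lipid-transfer protein genes that may share reads, rose by 0.96 ± 0.11 and 1.61 ± 0.30 (adjusted p = 2.87e-05 and 0.00693), and the receptor kinase genes CRK10 (AT4G23180) and CRK20 (AT4G23280) by 0.55 ± 0.083 and 1.64 ± 0.26 (adjusted p = 0.000209 and 0.000305). MYB34 (AT5G60890), a regulator of indole glucosinolates, fell by 1.00 (SE 0.14, adjusted p = 0.000116).

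Of the pattern-triggered immunity list, 3 of 24 members were higher at W7 (3 over the list alone), as were 1221 of all 19404 genes. The counts of higher members were 3 of 23 for salicylic acid (3 over the list alone), 2 of 7 for systemic acquired resistance (2), 2 of 13 for camalexin (2) and 4 of 15 for the receptor kinases (5). Whether these shares exceed that of all genes was not tested. The list median of pattern-triggered immunity was 0.187, while its mean was -0.054. Without mock replicate 3 these counts were 13, 10, 3, 7 of 14 and 11, in the order given. Relative to mock replicates 1 and 2, the list medians of mock replicate 3 were 0.659 for pattern-triggered immunity (0.357 to 0.854 in the W7 libraries) and 1.41 for salicylic acid (0.376 to 1.74). The pattern-triggered immunity count was 5 without W7 replicate 1 and 1 without W7 replicate 2. The camalexin count was 0 without mock replicate 1 or 2 and 1 without W7 replicate 2 or 3. With DESeq2 the pattern-triggered immunity and salicylic acid counts were 5 and 5, limma voom gave 5 for salicylic acid, and in a fit of only these 2 groups the salicylic acid and camalexin counts were 1 and 1. Camera called all 5 lists with the preset correlation (lowest adjusted p = 0.000101). With an estimated correlation it called none (adjusted p = 0.613 for each).

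Of the glucosinolate lists at W7, 2 of 10 indole members were higher and 1 lower (3 and 1 over the list alone), and 6 of 16 aliphatic members were lower (7 over the list alone). The indole count of calls was 1 without mock replicate 1 or 2 and 7 without mock replicate 3. The aliphatic count was 1 without mock replicate 1, 2 without W7 replicate 1 and 0 without W7 replicate 2. Light harvesting and carbon fixation had 4 of 21 members lower (5 over the list alone). The count was 0 without mock replicates 1 or 2 or W7 replicates 2 or 3, and 14 without mock replicate 3. Its count was also 0 in a fit of only these 2 groups, 2 with robust=FALSE, 2 with limma voom and 16 without mock replicate 3 and W8 replicate 2. Senescence had 4 of 7 members higher (5 over the list alone), NAP (1.32 ± 0.12, adjusted p = 2.71e-06), ORE1, PAO and PPH. The clock had 3 members higher and 4 lower of 11 (4 and 4 over the list alone), with 4 calls without W7 replicate 2 and 4 in a fit of only these 2 groups. The lower ones included the morning genes CCA1 (-0.60 ± 0.096, adjusted p = 0.000516) and PRR9 (-0.77 ± 0.09, adjusted p = 1.12e-05). Aliphatic glucosinolates (adjusted p = 0.00132), light harvesting (0.000101) and senescence (3.44e-05) were called by camera with the preset correlation. With an estimated correlation they were not (adjusted p = 0.613, 0.613 and 0.141 with an estimated correlation).

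At W7 single members of 4 further lists were higher: the jasmonic acid repressor gene JAZ9 (AT1G70700; 1.16 ± 0.23, adjusted p = 0.00855), the iron deficiency regulator BHLH101 (AT5G04150, uncertain because of shared exon bases; 2.28 ± 0.53, adjusted p = 0.00787), the auxin-conjugating GH3.5 (AT4G27260; 0.96) and the nitrate transporter NRT2.1 (AT1G08090; 2.02). Over the list alone 1 member passed in each of these lists. BHLH101 had an adjusted p of 0.0553 without mock replicate 2, and GH3.5 of 0.0658, 0.0714 and 0.0726 without mock replicates 1 and 2 and W7 replicate 2. The jasmonic acid count was 4 without mock replicate 3, 2 without W7 replicate 1, 2 with DESeq2, 3 with robust=FALSE, 2 with limma voom and 2 in a fit of only these 2 groups, where the iron count was 5. The auxin count was 2 with DESeq2 and 2 with robust=FALSE. For jasmonic acid camera gave adjusted p = 0.0481 (0.613 with an estimated correlation). The lists of ethylene, endoplasmic reticulum protein folding, heat shock, abscisic acid, phosphate starvation, flavonoids, cell cycle and flower markers had 0 members called by edgeR. At an unadjusted p under 0.05 they had 2, 4, 2, 3, 2, 2, 0 and 2, with DESeq2 0, 3, 1, 1, 0, 0, 0 and 0, and with limma voom 1, 1, 0, 1, 0, 0, 0 and 0. Over the list alone, 4 folding genes were higher (CRT3, AT1G08450; BIP3, AT1G09080; PDIL1-1, AT1G21750; SDF2, AT2G25110), and HSP101 (AT1G74310) and SEP3 (AT1G24260) were lower. Without mock replicate 3, members called were 4 for ethylene, 2 for folding, 1 for abscisic acid, 4 for phosphate starvation and 2 for flavonoids. Without W7 replicate 1 they were 1 for ethylene, 3 for folding and 1 for abscisic acid, and without mock replicate 1 they were 1 for heat shock and 1 for flower markers. With robust=FALSE they were 2 for folding and 1 for abscisic acid, without the filter 1 for folding, and with upper-quartile scaling 1 each for heat shock, flavonoids and flower markers.

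At W8, the highest density, PR1 (AT2G14610), a marker of salicylic acid signalling, stood at 75.5 ± 42.6 CPM against 0.304 ± 0.527 in mock (log2 fold change 7.79 ± 1.25, adjusted p = 0.000691). LURP1 (AT2G14560), a defence gene induced by oomycetes, rose by 4.94 ± 0.82 (adjusted p = 0.000865), from 13.8 ± 11.8 to 435 ± 71 CPM. FRK1 rose by 4.49 ± 0.35 (adjusted p = 4.53e-06), from 4.81 ± 2.6 to 110 ± 29.5 CPM. DLO1 (AT4G10500), an enzyme that breaks down salicylic acid, rose by 4.82 ± 0.87 (adjusted p = 0.00136), and SAG13 (AT2G29350), a gene of senescence and defence, by 4.50 ± 0.82 (adjusted p = 0.00153). BT2 reached 115 ± 22.8 CPM (4.71 ± 0.21, adjusted p = 1.17e-08), AT2G17740 rose by 4.90 ± 0.42 (adjusted p = 3.49e-06) and AT3G28510, which encodes an ATPase-like protein, by 5.18 ± 1.24 (adjusted p = 0.00756). AT4G12490, a lipid-transfer protein gene beside AZI1 and EARLI1, rose by 5.86 ± 0.81 (adjusted p = 0.00025), and AT3G18250 by 4.86 ± 0.54 (adjusted p = 3.39e-05), both uncertain because of shared exon bases. PR1 and AT3G28510 were at 0 in mock replicates 1 and 2, and at 0.913 and 0.685 CPM in mock replicate 3. Without that library their fitted changes of 13.57 and 10.52 (adjusted p = 0.00297 and 0.00778) depend on the prior count and measure no size.

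The falls at W8 were smaller. AT2G15020 fell by 3.59 on the log2 scale (SE 0.31, adjusted p = 7.31e-06), AT2G44940 by 2.48 (SE 0.13, adjusted p = 2.85e-10) and BBX29 by 2.25 (SE 0.17, adjusted p = 1.69e-08). XTH31 (AT3G44990), a cell wall xyloglucan enzyme gene, fell by 2.05 (SE 0.21, adjusted p = 2.5e-05), from 124 ± 35.7 to 29.9 ± 2.38 CPM. AT3G28270 fell by 2.05 (SE 0.24, adjusted p = 2.63e-06), AT5G55620 by 1.96 (SE 0.084, adjusted p = 7.02e-12) and AT1G76240 by 1.88 (SE 0.12, adjusted p = 1.87e-09).

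In all, 6896 genes passed at W8, 3588 higher and 3308 lower, and 8551 had an unadjusted p under 0.05. At least 2-fold changes were found for 1094, with 845 higher and 249 lower. The split depended on the scaling: with upper-quartile scaling 2877 were higher and 4299 lower, 40.1% higher against 52% with TMM.

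**Figure D2:**
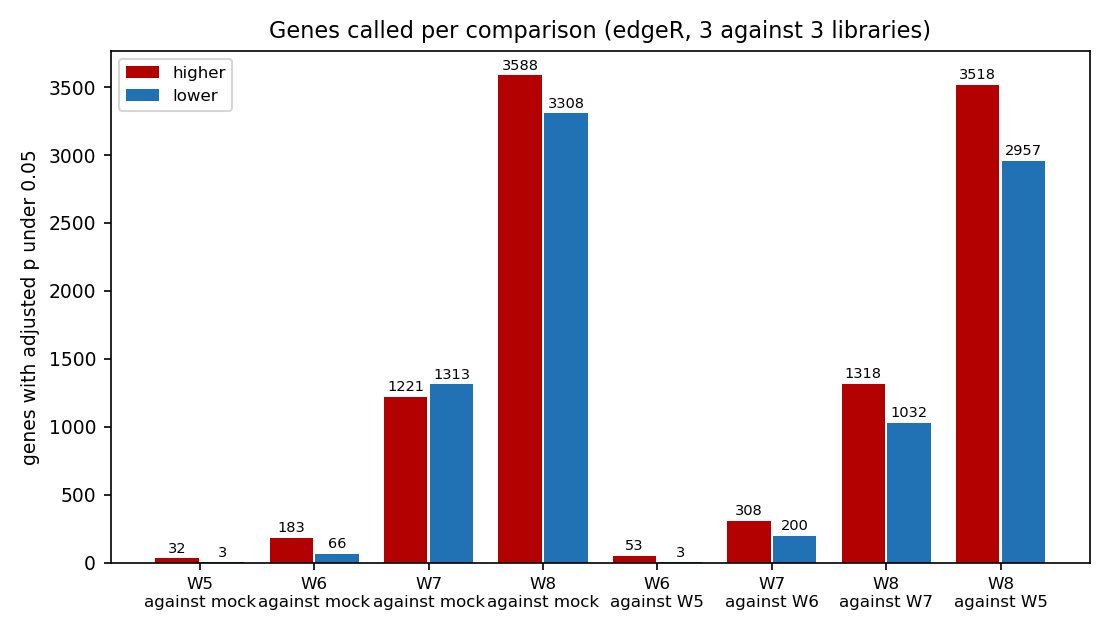
Bars give the genes called higher (up) and lower (down) by edgeR in each comparison. Against mock the calls grow from 35 at W5 to 6896 at W8.

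Immune list members were called higher at W8. In the pattern-triggered immunity list 13 of 24 members were higher and 0 lower (15 over the list alone), with PUB22 (AT3G52450), a ubiquitin ligase, at 1.32 ± 0.20 (adjusted p = 4.21e-05), the co-receptor BAK1 (AT4G33430) at 0.53 ± 0.081 (adjusted p = 5.02e-05) and the kinase MPK3 (AT3G45640, uncertain because of shared exon bases) at 0.61 ± 0.096 (adjusted p = 8.8e-05). In the salicylic acid list 18 of 23 were higher and 0 lower (19 over the list alone). Among them NPR4 rose by 1.15 ± 0.098 (adjusted p = 6.22e-08), NPR3 by 1.49 ± 0.16 (adjusted p = 9.4e-06), SAG101 (AT5G14930) by 0.76 ± 0.12 (adjusted p = 6.83e-05) and the glucanase gene PR2 (AT3G57260) by 3.04 ± 0.58 (adjusted p = 0.00203). Systemic acquired resistance had 5 of 7 higher (5 over the list alone), with AZI1 at 1.98 ± 0.11 (adjusted p = 5.04e-09), EARLI1 at 3.16 ± 0.31 (adjusted p = 2.16e-05) and LLP1 (AT5G03350), a lectin, at 3.36 ± 0.73 (adjusted p = 0.00449). Camalexin had 9 of 13 higher (9 over the list alone), with GSTF6 (AT1G02930) at 2.61 ± 0.24 (adjusted p = 1.18e-05), from 92.1 ± 16.5 to 564 ± 87.1 CPM, and PAD3 (AT3G26830), the last enzyme of camalexin synthesis, at 4.07 ± 0.91 (adjusted p = 0.00522) and 6.18 without mock replicate 3. The receptor kinase list had 14 of 15 higher (14 over the list alone), with CRK20 at 3.03 ± 0.25 (adjusted p = 4.6e-08) and CRK5 (AT4G23130) at 1.92 ± 0.14 (adjusted p = 1.73e-08), members of a tandem cluster that may share reads. Endoplasmic reticulum protein folding had 9 of 13 higher (10 over the list alone), with CRT3 at 1.24 ± 0.15 (adjusted p = 3.62e-05) and PDIL1-1 at 0.66 ± 0.086 (adjusted p = 9.77e-06).

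Camera called these 6 lists with the preset correlation (adjusted p from 2e-09 to 0.000157). With an estimated correlation it called none (adjusted p = 0.41 for pattern-triggered immunity, 0.433 for folding and 0.343 for the others). Several immune genes did not pass against all 3 mock libraries and passed without mock replicate 3. ICS1 (AT1G74710), the main salicylic acid synthesis gene, had a log2 fold change of 0.75 (adjusted p = 0.0758) and 1.17 without it (0.00514). WRKY33 (AT2G38470) had 1.11 (0.0947) and 2.12 without it (0.000105), CYP71A13 (AT2G30770, uncertain) 2.58 (0.106) and 7.24 without it (0.00237), and FMO1 (AT1G19250), which makes N-hydroxypipecolic acid, 1.03 (0.587) and 5.17 without it (0.0248). With robust=FALSE and limma voom, ICS1 (0.0274 and 0.0157), WRKY33 (0.0349 and 0.00658) and CYP71A13 (0.0431 and 0.00711) also passed, and ICS1 passed with DESeq2 (0.0479). PR5 (AT1G75040) rose by 1.27 ± 0.39 (adjusted p = 0.027), but not without mock replicate 2 (0.0768), mock replicate 3 (0.0778) or W8 replicate 2 (0.117), nor in a fit of only these 2 groups (0.0778) or without mock replicate 3 and W8 replicate 2 (0.232). Mock replicate 3 lay above mock replicates 1 and 2 in the median of the immune lists, by 0.659 for pattern-triggered immunity and 1.93 for systemic acquired resistance, below the W8 libraries (1.23 to 1.84 and 3.94 to 4.72), of which W8 replicate 2 was the highest in both.

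**Figure D3:**
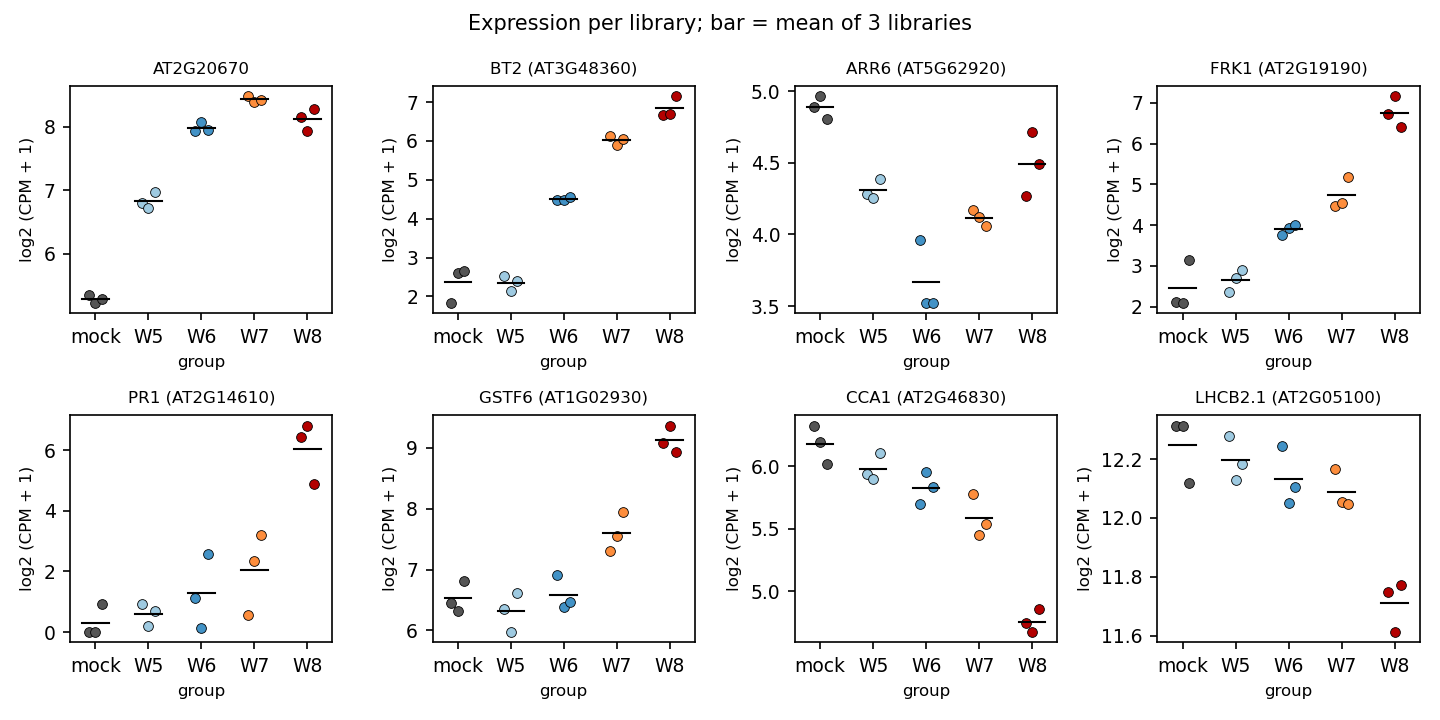
Each panel plots 1 gene as log2(CPM + 1) in every library, by group, for AT2G20670, BT2, ARR6, FRK1, PR1, GSTF6, CCA1 and LHCB2.1. AT2G20670 rises from 38.1 CPM in mock to 113 at W5, whereas PR1 stands at 4.28 CPM at W7 and 75.5 at W8.

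Of the indole glucosinolate list 7 of 10 members were higher and 1 lower at W8 (7 and 1 over the list alone), with MYB51 (AT1G18570), which the camalexin list also holds, at 1.85 ± 0.20 (adjusted p = 2.23e-05), CYP83B1 (AT4G31500) at 0.78 ± 0.10 (adjusted p = 1.62e-05) and the myrosinase PEN2 (AT2G44490) at 0.57 ± 0.076 (adjusted p = 1.22e-05). The lower one was MYB34 at -1.74 ± 0.15 (adjusted p = 7.64e-08). Of the aliphatic glucosinolate list 0 of 16 were higher and 13 lower (13 over the list alone), with the regulator MYB28 (AT5G61420) at -0.68 ± 0.11 (adjusted p = 9.1e-05), SOT18 (AT1G74090) at -0.81 ± 0.10 (adjusted p = 1.81e-05) and CYP79F2 at -0.78 ± 0.11 (adjusted p = 1.3e-05; uncertain beside its close copy CYP79F1). Camera gave adjusted p = 0.00346 for the indole list and 1.58e-06 for the aliphatic list (0.343 for each with an estimated correlation).

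Few members of the hormone and stress lists passed at W8. In the jasmonic acid list 1 of 20 was higher, JAZ9 (0.69 ± 0.23, adjusted p = 0.0371), with 0 over the list alone. The count was 0 without mock replicates 1 or 2 or W8 replicates 1, 2 or 3 (adjusted p of JAZ9 0.0555, 0.123, 0.108, 0.0545 and 0.0783) and 7 without mock replicate 3 (6 higher, 1 lower). By unadjusted p under 0.05 it was 4, with DESeq2 1, with limma voom 3, with robust=FALSE 3, in a fit of only these 2 groups 3 and without the filter 0. JAZ9 had adjusted p values of 0.0507 without the filter, 0.0539 with upper-quartile scaling and 0.0605 without mock replicate 3 and W8 replicate 2. VSP2 (AT5G24770) had a log2 fold change of 0.18 ± 0.78 (adjusted p = 0.886), below 0 without mock replicate 2 or W8 replicate 3. The ethylene list had 3 of 11 higher (3 over the list alone): HEL (AT3G04720; 1.1 ± 0.25, adjusted p = 0.00556), ERF5 (AT5G47230; 0.50 ± 0.17, adjusted p = 0.0287) and the chitinase HCHIB (AT3G12500, uncertain; 0.89 ± 0.30, adjusted p = 0.0325). The ethylene count was 1 without mock replicate 1, mock replicate 2, W8 replicate 1 or W8 replicate 3, 7 without mock replicate 3 and 1 in a fit of only these 2 groups, where ERF5 and HCHIB had adjusted p values of 0.0531 and 0.0998. ERF5 had 0.0518 with upper-quartile scaling, and HCHIB 0.0529 without the filter and 0.0573 with limma voom. PDF1.2 (AT5G44420) had 0.50 ± 0.78 (adjusted p = 0.67). In mock replicate 3 the ethylene list stood at a median of 1.58, against 1.1 to 1.89 in the W8 libraries.

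Of 7 heat shock members, HSP90.1 (AT5G52640) was higher (0.46 ± 0.13, adjusted p = 0.01) and HSP101 lower (-0.56 ± 0.17, adjusted p = 0.0147), 1 and 1 over the list alone. HSP90.1 had adjusted p values of 0.0537, 0.0659 and 0.0558 without mock replicates 1 and 2 and W8 replicate 2, and HSP101 of 0.0972, 0.0508 and 0.0621 without mock replicate 3 and W8 replicates 1 and 2, and 0.221 without mock replicate 3 and W8 replicate 2 together. Of 13 abscisic acid and cold or drought members, RD29B (AT5G52300) was higher, at 0.0797 ± 0.0712 CPM in mock and 0.696 ± 0.0893 at W8 (adjusted p = 0.00173), and COR15A (AT2G42540) lower (-0.65 ± 0.20, adjusted p = 0.0215), 1 and 1 over the list alone. COR15A had 0.082, 0.0545 and 0.0855 without mock replicates 1 and 2 and W8 replicate 2, and 0.0591 without mock replicate 3 and W8 replicate 2, and 1 member was called with the stricter filter. The median of this list was -0.0341, while its mean was 0.337 and camera gave the direction as up. Camera did not call the jasmonic acid, ethylene, heat shock or abscisic acid lists (adjusted p = 0.589, 0.0699, 0.589 and 0.875).

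Photosynthesis genes fell together at W8: 21 of 21 members of the light harvesting and carbon fixation list were lower (21 over the list alone), with a median log2 fold change of -0.486. RBCS3B, a Rubisco small subunit gene, fell by 0.82 (SE 0.11, adjusted p = 1.82e-05), rubisco activase RCA (AT2G39730) by 0.70 (SE 0.11, adjusted p = 4.79e-05) and GAPB (AT1G42970) by 0.72 (SE 0.11, adjusted p = 4.8e-05). LHCB2.1 (AT2G05100) fell by 0.54 (SE 0.08, adjusted p = 3.96e-05), from 4870 ± 371 to 3360 ± 197 CPM, and LHCB1.1 (AT1G29920) by 0.44 (SE 0.086, adjusted p = 0.000484). RBCS and LHCB genes have near-identical copies, so single members are uncertain. In all, 1 of the 21 fell at least 2-fold. Camera gave adjusted p = 6.07e-10 (0.343 with an estimated correlation). The list median of mock replicate 3 was -0.258, against -0.64 to -0.489 in the W8 libraries.

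Some nutrient list members were lower at W8. Phosphate starvation had 0 of 14 higher and 6 lower (8 over the list alone), with SPX1 (AT5G20150), a phosphate sensor gene, at -1.68 ± 0.33 (adjusted p = 0.00221). The count was 1, 2 and 9 without mock replicates 1, 2 and 3. It was 2 without W8 replicates 1 or 2 and in a fit of only these 2 groups. The phosphate median of mock replicate 3 was -0.757, against -0.845 to -0.436 in the W8 libraries. Iron deficiency had 3 of 10 lower (3 over the list alone): the peptide gene IMA3 (AT2G30766) at -2.32 ± 0.41 (adjusted p = 0.000185), BHLH38 (AT3G56970) at -2.59 ± 0.63 (adjusted p = 0.0034), both uncertain because of shared exon bases, and BHLH100 (AT2G41240), at 0.813 ± 0.403 CPM in mock and 0.0313 ± 0.0542 at W8 (adjusted p = 0.0316). BHLH100 had adjusted p values of 0.0526, 0.0977, 0.0965, 0.0678 and 0.089 without mock replicates 1 and 2 and W8 replicates 1, 2 and 3, 0.0504 without the filter and 0.103 without mock replicate 3 and W8 replicate 2. Camera gave adjusted p = 0.0193 for phosphate (0.639 with an estimated correlation) and 0.108 for iron.

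Flavonoids and anthocyanins had 4 of 13 members lower at W8 (4 over the list alone). CHI (AT3G55120) and F3'H (AT5G07990), enzymes of flavonoid synthesis, fell by 0.45 (SE 0.098, adjusted p = 0.00136) and 0.60 (SE 0.15, adjusted p = 0.00415), CHS (AT5G13930) by 0.96 (SE 0.33, adjusted p = 0.0408) and UGT75C1 (AT4G14090, uncertain) by 0.81 (SE 0.29, adjusted p = 0.0363). CHS had 0.131, 0.132, 0.0835, 0.13 and 0.0715 without mock replicates 1 and 2 and W8 replicates 1, 2 and 3, and UGT75C1 0.18, 0.17 and 0.0954 without mock replicate 1 and W8 replicates 2 and 3. CHS had 0.0562 without the filter, and CHS and UGT75C1 had 0.0686 and 0.0973 in a fit of only these 2 groups. UGT75C1 had 0.163 without mock replicate 3 and W8 replicate 2. Auxin response had 3 higher and 2 lower of 11 (3 and 2 over the list alone). GH3.5 rose by 1.63 ± 0.22 (adjusted p = 0.000103) and IAA19 (AT3G15540) by 0.50 ± 0.11 (adjusted p = 0.00144), the third being IAA6 (AT1G52830; 0.96, adjusted p = 0.042), chosen after its value was seen. IAA29 (AT4G32280) fell by 1.03 (SE 0.26, adjusted p = 0.00375) and IAA2 (AT3G23030) by 0.23 (SE 0.071, adjusted p = 0.0148). There were 3 auxin calls without mock replicate 2 or W8 replicate 1, and IAA2 had adjusted p values of 0.0963 and 0.0583 there. The cell cycle list had 0 of 10 members called by edgeR (0 over the list alone), 0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom, with 1 called by edgeR without W8 replicate 2, CYCB1;2 (AT5G06150; 0.48, adjusted p = 0.00939). Camera did not call the flavonoid, auxin or cell cycle lists (adjusted p = 0.0997, 0.875 and 0.875), and its direction was up for auxin, where the median was -0.0438, and down for the cell cycle, where it was 0.0317.

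All 7 senescence members tested were higher at W8 (7 over the list alone). Besides SAG13, NAP rose by 1.29 ± 0.12 (adjusted p = 9.85e-07), ORE1 by 1.3 ± 0.16 (adjusted p = 3.96e-05), and the chlorophyll breakdown genes PAO and NYC1 (AT4G13250) by 0.42 ± 0.06 and 0.34 ± 0.065 (adjusted p = 2.34e-05 and 0.000456). Camera gave adjusted p = 3.93e-05 (0.239 with an estimated correlation). Of the clock list 6 of 11 members were higher and 4 lower (6 and 4 over the list alone). The morning genes CCA1 and PRR9 fell by 1.46 (SE 0.1, adjusted p = 1.04e-08) and 1.33 (SE 0.092, adjusted p = 5.63e-09), and the evening genes LUX (AT3G46640, uncertain because of shared exon bases) and ELF3 (AT2G25930) rose by 1.04 ± 0.11 (adjusted p = 7.03e-07) and 0.55 ± 0.072 (adjusted p = 9.9e-06). Camera did not call the clock list (adjusted p = 0.875). The root and flower lists stood for tissues that the samples could hold. Of the root markers 3 of 7 passed the filter and 1 was higher (1 higher and 1 lower over the list alone), NRT2.1 (3.05 ± 0.35, adjusted p = 1.97e-06), which stood at 4.87 ± 2.29 CPM. PYK10 (AT3G09260, uncertain because of shared exon bases), an abundant root protein gene, had a log2 fold change of -0.16 ± 0.16 (adjusted p = 0.486), above 0 without W8 replicate 2. The root list median was -0.157 and its mean 0.792, and 3 root members were called without W8 replicate 3 and 2 with DESeq2 size factors, upper-quartile scaling, robust=FALSE or limma voom. Of the flower markers 4 of 8 passed the filter and 1 was lower (1 over the list alone), SEP1 (AT5G15800, uncertain), at 0.357 ± 0.252 CPM in mock and 0.0151 ± 0.0261 at W8 (adjusted p = 0.00219), and 2 were called without mock replicate 1. The flower count was 0 with the stricter filter, in a fit of only these 2 groups and without mock replicate 3 and W8 replicate 2 (adjusted p of SEP1 0.0704). Camera called neither list (adjusted p = 0.875 and 0.195).

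**Figure D4:**
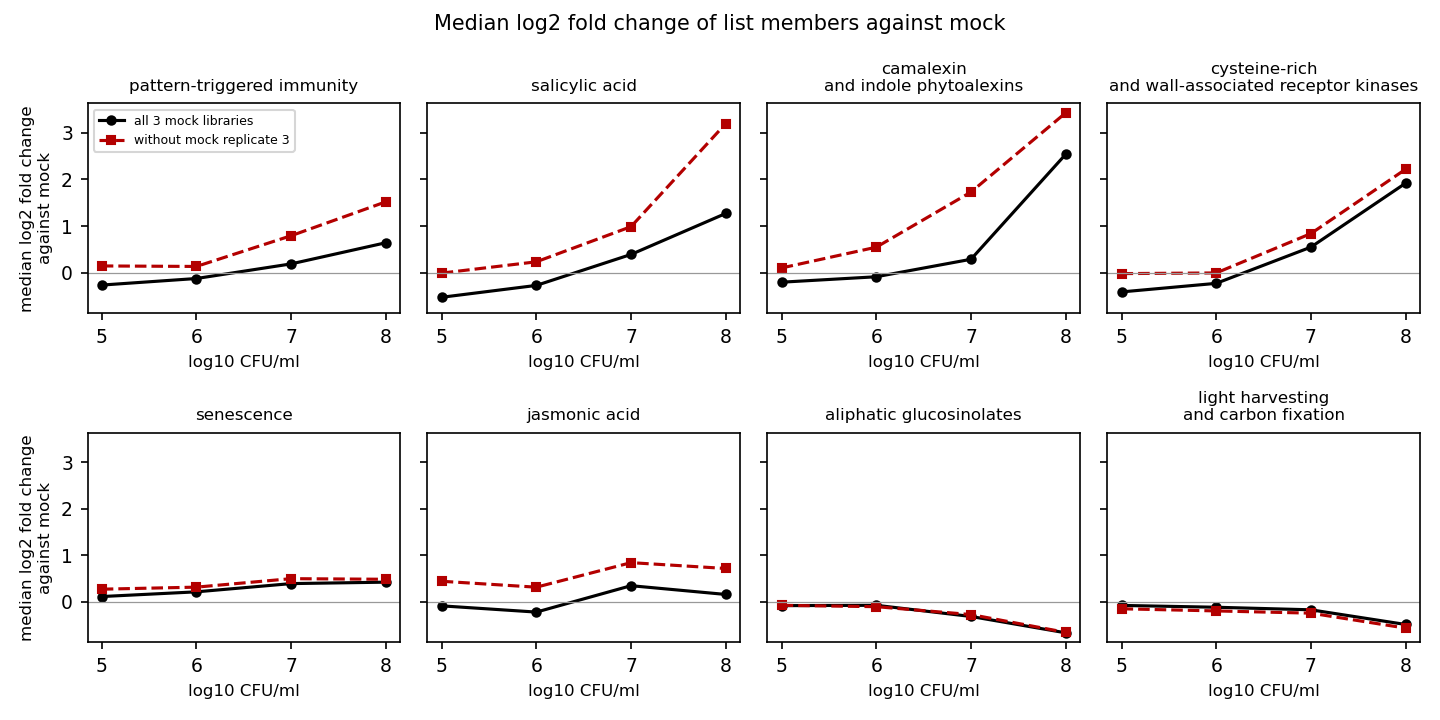
Each panel plots the median log2 fold change against mock of 1 gene list by log10 density, with all 3 mock libraries and without mock replicate 3. The salicylic acid list reaches 1.27 at W8 with all mock libraries and 3.2 without mock replicate 3, while light harvesting and carbon fixation falls to -0.486 and -0.564.

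The steps between neighbouring densities compare inoculated groups with each other, and the mock libraries enter only the spread estimated over all 15 libraries and the scaling and filter. From W5 to W6, BT2 rose by 2.39 ± 0.22 (adjusted p = 0.000295) and AT2G20670 by 1.16 ± 0.084 (adjusted p = 5.48e-07). ARR6 fell by 0.67 (SE 0.12, adjusted p = 0.016) and AT5G55620 by 0.46 (SE 0.079, adjusted p = 0.00877). ARR6 had adjusted p values of 0.0661, 0.0621, 0.101, 0.108 and 0.153 without W5 replicates 1, 2 and 3 and W6 replicates 2 and 3, and AT5G55620 of 0.089 and 0.0518 without W5 replicates 1 and 2. The 3 genes lower were these and AT1G33600, a leucine-rich repeat gene (-0.32 ± 0.058, adjusted p = 0.0154; uncertain because of shared exon bases), with 0.0659, 0.125, 0.0721 and 0.0825 without W5 replicates 1 and 3 and W6 replicates 2 and 3. In all, 56 genes passed, 53 higher and 3 lower, 3 of them at least 2-fold, with 1411 at an unadjusted p under 0.05. The count was 34, 30 and 31 without W5 replicates 1, 2 and 3, and 35 and 26 without W6 replicates 2 and 3. It was 117 with DESeq2, 122 in a fit of only these 2 groups and 137 without mock replicate 3 and W8 replicate 2.

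From W6 to W7, BT2 rose again by 1.57 ± 0.17 (adjusted p = 0.00182) and ABCG14 (AT1G31770), a transporter that loads cytokinin for the shoot, fell by 1.09 (SE 0.17, adjusted p = 0.00483). AT5G64190 rose by 1.34 ± 0.23 (adjusted p = 0.00733), with adjusted p values of 0.0547, 0.061 and 0.0521 without W6 replicates 1 and 3 and W7 replicate 2. In all, 508 genes passed, 308 higher and 200 lower, 31 of them at least 2-fold, with 3803 at an unadjusted p under 0.05. The count was 66, 1153 and 39 without W6 replicates 1, 2 and 3, and 55 and 110 without W7 replicates 2 and 3. It was 1041 with DESeq2 and 1424 without mock replicate 3 and W8 replicate 2. With upper-quartile scaling 234 were higher and 359 lower (39.5% higher against 60.6%).

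From W7 to W8, LUP5 (AT1G66960), a triterpene synthase gene, rose by 3.58 ± 0.72 (adjusted p = 0.00962), PR1 by 4.16 ± 0.88 (adjusted p = 0.0131) and DLO1 by 3.16 ± 0.75 (adjusted p = 0.0211). PR1 had adjusted p values of 0.0515, 0.0543 and 0.0626 without W7 replicates 1 and 2 and W8 replicate 2, and DLO1 of 0.0632, 0.086 and 0.0975 without the same libraries. In a fit of only these 2 groups they had 0.0677 and 0.0878, and with DESeq2 PR1 had 0.05. AT2G15020 fell by 1.74 (SE 0.33, adjusted p = 0.00637) and CLC-B (AT3G27170), an anion channel gene that shares exon bases, by 1.43 (SE 0.24, adjusted p = 0.000816). In all, 2350 genes passed, 1318 higher and 1032 lower, 300 of them at least 2-fold, with 5051 at an unadjusted p under 0.05. The count was 1038 and 1552 without W7 replicates 1 and 2, and 1098 without W8 replicate 2. With upper-quartile scaling 1052 were higher and 1447 lower (42.1% higher against 56.1%). Between the ends, W8 against W5, 6475 genes passed, 3518 higher and 2957 lower, 1161 of them at least 2-fold, and with upper-quartile scaling 2836 were higher and 4036 lower (41.3% higher against 54.3%).

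Across the 12 inoculated libraries, slopes on log10 density were fitted for each gene. PR1 rose by 2.70 ± 0.37 per 10-fold density (SE, adjusted p = 0.000289), DLO1 by 2.71 ± 0.30 (adjusted p = 4.33e-05), LUP5 by 2.59 ± 0.27 (adjusted p = 3.33e-05), AT3G28510 by 2.88 ± 0.37 (adjusted p = 0.000147) and AT4G11170, an immune receptor gene of the TIR-NBS-LRR class, by 2.77 ± 0.46 (adjusted p = 0.000954). The slope of AT4G11170 was 1.65 without W8 replicate 2, and it also stood at 7.67 ± 13.3 CPM in mock. The steepest falls were those of AT2G15020 (-0.99 ± 0.087, adjusted p = 5.37e-06), AT5G20790 (-0.87 ± 0.21, adjusted p = 0.00665), BBX29 (-0.69 ± 0.05, adjusted p = 3.71e-08), SPX1 (-0.67 ± 0.072, adjusted p = 2.98e-05) and AT2G44940 (-0.63 ± 0.039, adjusted p = 4.88e-09). In all, 6699 of 19285 genes passed, 3734 higher and 2965 lower. With upper-quartile scaling 3018 were higher and 4163 lower (42% higher against 55.7%).

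Most immune list members rose with density: 23 of 23 for salicylic acid (23 over the list alone), 15 of 15 for the receptor kinases (15), 7 of 7 for systemic acquired resistance (7), 19 of 24 for pattern-triggered immunity (19), 11 of 13 for protein folding (11), 10 of 13 for camalexin (11) and 6 of 11 for ethylene (6, but 3 with mock to W8 scored 0 to 4). FRK1 rose by 1.44 ± 0.10 per 10-fold density (adjusted p = 3.03e-06). Senescence had 7 of 7 members rising (7). Light harvesting and carbon fixation had 20 of 21 falling (21) and aliphatic glucosinolates 12 of 16 (14), while the indole list had 7 rising and 1 falling of 10 (8 and 1) and the clock 5 and 3 of 11 (5 and 4). The steepest slopes in the clock list were those of CCA1 (-0.39) and PRR9 (-0.39). Camera called 13 lists with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.051 with an estimated correlation, for senescence).

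The fold changes of the 4 densities share the mock libraries, so they were set beside simulations of unchanged groups. Across 19404 genes, which are not independent replicates, the correlation between W7 and W8 was 0.696 (0.692 on average in 100 simulations) and the covariance 0.179 (0.052), a difference of 0.127. For W5 and W6 the correlation was 0.699 (0.689) and the covariance 0.122 (0.0518), a difference of 0.0697. For W5 and W8 the correlation was 0.0159 (0.691) and the covariance 0.00431 (0.0518), a difference of -0.0475. The differences in covariance for W5 and W7, W6 and W7, and W6 and W8 were 0.03, 0.0461 and 0.0123. Of the 32 genes called higher at W5, 32 were higher at W6 and 30 at W8, where independent lists would share 0.302 and 5.92. Of the 183 higher at W6, 179 were higher at W7 (11.5 if independent). Of the 1221 higher at W7, 1119 were higher at W8 (226). Of the 1313 lower at W7, 1090 were lower at W8 (224). The simulated groups hold no changed genes, so they cannot gauge these shared counts. The W5 and W6 count was 16, 18 and 49 without mock replicates 1, 2 and 3. It was 15 and 17 without W5 replicates 1 and 3. The W5 and W8 count was 15, 17, 48, 14 and 16 without the same libraries. The W6 and W7 count was 284 without mock replicate 3, and 119 without W6 replicate 2. The W7 and W8 counts of higher genes were 667, 636, 1798 and 676 without mock replicates 1, 2 and 3 and W7 replicate 2. Those of lower genes were 450, 380, 1653, 416 and 616 without the same libraries and W7 replicate 3. The 3 mock libraries cannot be split into groups of 2, so part of the excess over independent lists may come from the shared controls.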

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

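The comparison of successive steps gene by gene, the choice of 8 genes by the size of their second step among those with an average log2 CPM of at least 1, and the fit without mock replicate 3 and W8 replicate 2 together came after the results had been seen.

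Of the 643 genes that edgeR called both in W7 against mock and in W8 against W7, 338 rose in both steps and 235 fell in both. The others drew attention because they turned between the densities: 40 were higher at W7 than in mock and then lower at W8 than at W7, and 30 were lower and then higher. Each step passed its own test, and the difference between the steps was not tested. Both steps use the W7 libraries, with opposite signs, so a chance value of these libraries adds genes of this kind. The counts of higher then lower and lower then higher genes were 20 and 8 without W7 replicate 1, 19 and 7 without W7 replicate 2, 33 and 16 without mock replicate 1, 28 and 11 without mock replicate 2, 24 and 14 without W8 replicate 1 and 25 and 14 without W8 replicate 2. They were 59 and 15 in a fit of only the 2 groups, 47 and 20 with upper-quartile scaling, 42 and 20 without the filter, and 36 and 29 without mock replicate 3 and W8 replicate 2. Of the 70 genes, 13 kept both calls in all 19 alternatives. AT2G18190, AT4G36700, BHLH101 and AT5G55340, under an average of 1, had second steps of 3.54, -2.49, -2.27 and 1.65.

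Among genes that fell and then rose, CML42 (AT4G20780), a calmodulin-like calcium sensor, changed by -0.55 ± 0.11 from mock to W7 (log2, SE, edgeR adjusted p = 0.00267) and by 0.563 ± 0.109 from W7 to W8 (adjusted p = 0.00262), and kept both calls in all 19 alternatives. GLL22 (AT1G54000), a GDSL lipase-like gene with close relatives and for that reason uncertain, changed by -0.90 ± 0.23 and then 1.14 ± 0.23. Its first call was lost without mock replicate 1 (adjusted p = 0.0643), W7 replicate 1 (0.0527) or W7 replicate 3 (0.0575) and in a fit of only the 2 groups (0.0597), in a range of 0.00126 to 0.0643 over the alternatives. AT4G17670, a DUF581 family gene, changed by -0.61 ± 0.15 and then 0.634 ± 0.151. Its first step ranged from adjusted p = 0.00603 to 0.0962 and was lost without mock replicate 2 (0.0962) or W7 replicate 2 (0.0896), and its second from 0.00464 to 0.064, lost without W7 replicate 2 (0.0597) or W8 replicate 2 (0.064). AT3G23170 changed by -0.64 ± 0.13 and then 0.59 ± 0.134, and its second call ranged from adjusted p = 0.00141 to 0.0548, lost without W7 replicate 1 (0.0548) or W8 replicate 2 (0.0536).

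Among genes that rose and then fell, AT5G05890, a UDP-glycosyltransferase gene, changed by 0.54 ± 0.16 (edgeR adjusted p = 0.0366) and then -0.989 ± 0.167 (adjusted p = 0.00107). Its first call ranged from adjusted p = 0.00625 to 0.107 and was lost without mock replicates 1 (0.0896), 2 (0.0708) and 3 (0.074) and W7 replicates 1 (0.102) and 2 (0.107), each left out alone. AT5G54585 changed by 0.63 ± 0.15 and then -0.928 ± 0.147, and its first call ranged from 0.00291 to 0.0556, lost without mock replicate 2 (0.055) or W7 replicate 2 (0.0556). AT3G59710, a Rossmann-fold protein gene that is uncertain because of shared exon bases, changed by 0.80 ± 0.20 and then -0.74 ± 0.196. Its first call ranged from 0.00589 to 0.0569, lost without mock replicate 2 (0.0569), and its second from 0.0104 to 0.0774, lost without W7 replicate 1 (0.0772), W8 replicate 1 (0.0597) or W8 replicate 2 (0.0774). GH9B8 (AT2G32990), a glycosyl hydrolase gene, changed by 0.48 ± 0.14 and then -0.717 ± 0.144. Its first call ranged from 0.00681 to 0.134 and was lost without mock replicates 1 (0.0711), 2 (0.134) and 3 (0.0501) and W7 replicates 2 (0.0913) and 3 (0.121), each left out alone, and with upper-quartile scaling (0.0555).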

How the results depend on the processing

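The fit without mock replicate 3 and W8 replicate 2 together was chosen after seeing the data. No called change of a named gene reversed its direction in any alternative run. Changes that passed in neither fit took the other sign in 8 of 1236 fits with 1 library left out and 2 of 196 without mock replicate 3 and W8 replicate 2, for VSP2, PYK10, CYCB1;2, CDKB1;1, CDKB2;1 and PI at W8. The balance of higher and lower calls did turn, with upper-quartile scaling for W8 against mock, all comparisons of W7 and W8 with a lower density and the slope, and at W7 against mock without the filter, in a fit of only the 2 groups, with the 2-fold requirement and with any 1 of its libraries left out. The counts of genes for the slope and for any difference among the groups stayed within 1.5 times the reported value under the alternatives run for them, which left out the 2-fold requirement, and those for W8 against mock, W8 against W7 and W8 against W5 did so except with the 2-fold requirement or, for W8 against W7, with a library left out. With DESeq2 in place of edgeR, W5 against mock gave 58 genes, W6 against W5 117 and W7 against W6 1041. In a fit of only the 2 groups, W5 gave 14, W6 145 and W6 against W5 122. Without mock replicate 3 and W8 replicate 2, W5 gave 78, W6 577, W7 4158, W6 against W5 137 and W7 against W6 1424. The cause of these shifts was not tested. Requiring an absolute log2 fold change of at least 1 left 7, 57, 250 and 1094 genes at W5 to W8 against mock, and 3, 31, 300 and 1161 for W6 against W5, W7 against W6, W8 against W7 and W8 against W5, by its own construction. With 1 library left out, counts ran from 15 to 60 at W5, 147 to 469 at W6, 1120 to 3866 at W7, 5416 to 7511 at W8, 26 to 80 for W6 against W5, 39 to 1153 for W7 against W6, 1038 to 2156 for W8 against W7, 5046 to 5837 for W8 against W5, 5446 to 6894 for the slope and 4904 to 7178 for any difference. The highest values against mock came without mock replicate 3. With an estimated correlation camera called 0 lists at W5, W6, W7 and W8 and for the slope, and without mock replicate 3, with the preset correlation, 5, 5, 14 and 12 lists at W5 to W8.

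The replicate numbers did not pair the libraries: of 30 same-numbered pairs 6 had deviations from their group means with a correlation over 0.1 across genes (-0.305 to 0.32, median 0.045, against -0.016 for other pairs), and 7 of 15 libraries correlated best with their own number. With the replicate block the counts were 30, 230, 2650 and 6893 at W5 to W8, 63, 450, 2476 and 6506 for the steps and ends in the order above, 6551 for the slope and 6372 for any difference, with 6, 5, 9, 12 and 13 lists. Of 196 gene results under the block, 181 kept their side of the threshold, 8 lost a call and 7 gained one. Those lost included ARR6 at W5 (adjusted p = 0.0826) and CHS at W8 (0.0646), and AT5G05890 lost its call at W7 (0.0565). Members called moved from 6 to 3 for phosphate starvation at W8 and from 4 to 7 for light harvesting at W7.

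Of the named gene results, 188 of 192 kept their side of the threshold with DESeq2, 195 of 196 with DESeq2 size factors, 189 of 196 with upper-quartile scaling, 188 of 196 without the filter, 194 of 194 with the stricter filter, 183 of 196 with robust=FALSE and 179 of 196 with limma voom. In a fit of only the 2 groups 155 of 183 did, and 27 lost a call. With 1 library left out 1068 of 1236 did, 154 lost a call and 14 gained one, and without mock replicate 3 and W8 replicate 2 175 of 196 did. Under the other scalings the median log2 fold change of all genes was farthest from 0 at -0.0729, for W8 against W5 with upper-quartile scaling. The filter removed 13429 of 32833 genes, and how many of these greater depth would bring back was not tested.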

Other observations

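The sugar starvation and cytokinin lists, the swap test of mock replicate 3, both tests of the clock score and the test of genes at 0 were chosen after the results they concern had been seen, as was the fit without mock replicate 3 and W8 replicate 2 together.

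Of the genes that plants switch on when sugar runs short, more were called higher at each higher density. Of 21 such genes tested, edgeR called 1 higher at W5, 7 at W6, 17 at W7 and 18 at W8 against mock, with medians of 0.0395, 0.66, 1.5 and 1.74 on the log2 scale, and 20 rose with density over the inoculated libraries. DIN10 (AT5G20250), a raffinose synthase family gene induced by darkness, rose by 0.87 ± 0.12 at W6 (SE, edgeR adjusted p = 0.000403) and 1.48 ± 0.12 at W7 (adjusted p = 4.25e-07). TPS8 (AT1G70290), a member of the trehalose phosphate synthase family, rose by 0.92 ± 0.087 at W6 (edgeR adjusted p = 2.03e-06) and 1.63 ± 0.088 at W7 (adjusted p = 2.98e-10), and BZIP1 (AT5G49450), a transcription factor of the starvation response, by 1.3 ± 0.20 at W6 (adjusted p = 0.00484, but 0.292 in a fit of only the 2 groups). Without mock replicate 3 the count of the 21 was 3 at W5. Without mock replicate 3 and W8 replicate 2 it was 3 at W5 and 11 at W6. A candidate explanation is a shortage of sugar in the leaves at the higher densities. The prediction, written before the test, was that those 14 rise from W5 to W6 while the pattern-triggered immunity and salicylic acid lists do not. Those 14 had a median of 0.455 and a limma camera p of 4.8e-09 (p = 0.0271 with an estimated correlation), with 1 of them called by edgeR, against camera adjusted p values of 0.404 and 0.449 for the immune lists. The difference between the lists was not itself tested. Mixed splits of the same 6 libraries gave those 14 a camera p of 4.18e-06, 2.95e-05, 0.00122, 0.00769 and 0.0301, and otherwise 0.186 to 0.838. The first had higher values on the side of W5 replicate 1 and W6 replicates 2 and 3. Wrong groupings can thus fall under 0.05, so the test cannot decide the prediction, though the real p was lowest. With each library left out in turn, the p of the real groups stayed between 1.62e-11 and 3.09e-05. Many of these genes also vary with time of day, and sugar contents were not analysed here.

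Genes that report cytokinin signalling were among those lower than mock at each density. Of 9 tested, edgeR called 1, 4, 7 and 5 lower at W5 to W8 (medians -0.381, -0.54, -0.65 and -0.40). The 6 not seen among the largest changes had 0, 1, 4 and 3 called (medians -0.247, -0.413, -0.45 and -0.278). From W5 to W6 the 9 had a median of -0.148 and a limma camera p of 0.00226 (p = 0.109 with an estimated correlation). Only ARR6 was called lower, a call lost without any 1 W5 library or W6 replicate 2 or 3. Over the inoculated libraries 2 members rose with density and 2 fell. The rising count was 1 with upper-quartile scaling, without the filter and with limma voom, 0 with mock to W8 scored 0 to 4, and 1 without W5 replicate 1, any W6 library, W7 replicates 2 or 3 or W8 replicates 2 or 3, and the falling count was 1 without W5 replicate 2 or W8 replicates 2 or 3 and 0 without W8 replicate 1. ARR16 (AT2G40670) fell by 0.66 (SE 0.12, edgeR adjusted p = 0.00172) at W7 and ARR15 (AT1G74890) by 0.95 (SE 0.18, adjusted p = 0.000507) at W8, both response regulators induced by cytokinin. The call at W5 was ARR6, uncertain because of shared exon bases. The count of the 9 there was 0 without mock replicate 1 or 2 or any W5 library and with robust=FALSE. It was 2 with DESeq2, upper-quartile scaling or only the 2 groups. The count at W6 was 2 without mock replicate 3 or W6 replicate 2 and in a fit of only the 2 groups, that at W7 was 4 without mock replicate 2, and that at W8 was 3 without mock replicate 3 (with 1 higher) or W8 replicate 1. The prediction, written before the test, was that those 6 fall with density over the inoculated libraries. It was not met: their limma camera p was 0.414, with a median slope of -0.047. Against mock the same 6 were lower at W5, W6 and W7 (camera p = 8.77e-05, 2.52e-05 and 0.00012, or p = 0.0123, 0.00834 and 0.0135 with an estimated correlation) and at W8 had p = 0.0542 (0.165 with an estimated correlation).

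Mock replicate 3 lay 0.601 from the mean of the other mock libraries (root mean square over genes, log2 CPM), where mock replicates 1 and 2 lay 0.41 and 0.388 from theirs, and it had 52 genes over 2-fold above every other library. AOX1D (AT1G32350), an alternative oxidase gene chosen after its values were seen, stood at 101 CPM there, against 0.279 and 0.255 in the other mock libraries and 67.7 in W8 replicate 2. A swap with a library of W6, W7 or W8 would leave 1 of these nearer to mock replicates 1 and 2 than to its own group, and 0 were. Exposure to the bacterium at W6 or above would raise the 53 genes that rose from W5 to W6. These lay 0.156 above mock replicates 1 and 2 (median), below the 0.351 of W5 and the 0.971 of W6. The 95% bootstrap interval (0.0906 to 0.203) is over genes of 1 library, so exposure is not excluded. A stress unrelated to the spray or a library from outside the series may explain mock replicate 3, and neither was tested.

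The clock score of a library, the mean log2 CPM of the evening genes TOC1, PRR5, LUX and ELF3 minus that of the morning genes CCA1, LHY and PRR9, was -0.184 ± 0.217 in mock (SD, n = 3), 0.232 ± 0.0947 at W5, 0.492 ± 0.181 at W6, 1.01 ± 0.192 at W7 and 2.01 ± 0.0318 at W8. The lowest W8 library lay 2.03 above the highest mock library. Groups harvested in turn through the day could give this order. The labels give no time of day, so density and harvest time cannot be told apart for these or other density trends. A general stress state could also shift the clock, but mock replicate 3 scored 0.213 above the mean of the other mock libraries, and 1 library excludes nothing. An effect of the bacterium on the clock stays open as well.

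Of the 487 protein-coding genes with under 5% of exon bases of their own, 444 (91.2%) were at 0 in all 15 libraries, against 32.9% of those with 5% to 50%, 5.53% with 50% to 95% and 14.8% with at least 95%. Counting that leaves out reads on exons shared by overlapping genes may account for this. Among the list members at 0 were MYC2 (AT1G32640; 1.46% of exon bases of its own), F3H (AT3G51240; 6.17%) and DIR1 (AT5G48485; 0%), so their values of 0 say nothing of their expression. The list member EXPA7 (AT1G12560), a root hair gene at 97.9%, was also at 0.

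Other splits of the same libraries were compared with the real groups. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. In each of the 8 comparisons the real split gave the most genes. The real count and the highest of the other splits were 35 and 0 for W5, 249 and 10 for W6, 2534 and 97 for W7 and 6896 and 0 for W8 against mock. They were 56 and 0 for W6 against W5, 508 and 0 for W7 against W6, 2350 and 0 for W8 against W7 and 6475 and 0 for W8 against W5. Of 100 splits, only the real one reached 6699 genes for the slope (highest other 2587) or 6380 for any difference (highest other 2420). Chance was unlikely but not excluded, as 100 splits are few and mixed ones hold density differences within groups. Camera with the preset correlation called as many lists as in the real groups in 8 of 10 splits at W5 (real 6, highest other 10), 9 at W6 (6, 12), 5 at W7 (9, 13) and 4 at W8 (11, 15). For the slope, 12 of 100 splits called as many lists as the real 13 (highest other 15), so this count did not stand out.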
